A study of Mus musculus with 12 samples.

How the data were processed

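RNA was sequenced from 12 mouse samples: brain and placenta of wild-type and Nsd1 heterozygous embryos at embryonic day 19.5, with 3 libraries in each of 4 groups. The authors deposited a table of raw counts per gene for each tissue, with 1 column per library and 78261 rows named by Ensembl gene identifiers. Per the labels, total RNA was column-purified and made into libraries with an mRNA sequencing kit. The submitters' processing notes name the genome builds GRCm38 and mm10 and no aligner or counting tool. Whole numbers in every cell and column totals of 6970735 to 10467729 in brain and 7662730 to 10757698 in placenta were checked in the deposited counts. The growth and treatment texts of the labels describe a cultured cell line, while title, source and design name tissues, and the samples were taken as tissues.

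The row labels were tested before any gene name was used, because rows labelled with ubiquitous genes held almost no reads. Of the identifiers, 65.82% are in GENCODE release M21 on GRCm38, and those rows held 87.89% of the counts. For windows of 100 consecutive genes, the profile of counts was compared with annotated exons, weighted by their gene's number of transcripts, at every offset up to 1.5 Mb along the chromosome, in steps of 200 bp. The offset with the highest correlation was kept, and windows with close offsets were merged into 104 segments on the autosomes and X. A row was resolved when, at its segment's offset, at least 80% of its exonic overlap and at least 100 bp fell on a single M21 gene, called its source gene below, in a segment with a correlation of at least 0.6 over at least 50 genes, and with the same gene at offsets 300 bp to either side. That left 10622 resolved rows, 8490 of them with at least 10 counts, which held 57.05% of all counts and stood for 6777 source genes. The method was tested on simulated data with known shifts, where 98.92% of the rows of chromosome 19 and 99.17% of those of chromosome 12 were placed within 300 bp. There the rows were exons of M21 itself. The median best correlation was 0.733 and 0.818, against 0.609 and 0.681 for the highest over 5 kb away. In the data these lay closer, at 0.743 and 0.672. The simulation was thus easier than the data and gives no error rate for the gene names. Where several rows share a source gene, the row with the most counts stands for it in gene lists and among the 12 largest changes named in each direction. Unresolved rows were tested and counted but are not named.

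Differential expression was tested separately in each tissue with edgeR 4.0.16 in R 4.3.3, as heterozygote against wild type. Rows with low counts were removed with filterByExpr, libraries were scaled with TMM, and a quasi-likelihood model was fitted. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method over all rows tested, and rows with an adjusted p under 0.05 were called. The difference between tissues was tested as the interaction of genotype and tissue in a fit of all 12 libraries. Levels are given as CPM, the counts in every 1000000 counts of a library, scaled with TMM unless said otherwise, and errors of means are SD over 3 libraries. Log2 changes are edgeR estimates, heterozygote minus wild type, with the SE of the coefficient. With 3 libraries in each group, an exact permutation test of a single row could not go below 0.10, so all p-values rest on the spread that edgeR shares between rows.

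Before the data were examined, 43 gene lists, the tests and the rule for named genes were fixed. The rule names Nsd1, the 12 largest changes in each direction among called rows that have gene symbols, with predicted genes (Gm followed by digits, or ending in Rik) left out, an average of at least 1 log2 CPM and no overlap between groups, and up to 4 members of each list. Lists with at least 5 tested members were compared with all other rows by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a correlation preset to 0.01. The calls were repeated with an estimated correlation and with fry. Overlap between tissues was tested with a one-sided Fisher exact test over the rows tested in both.

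The edgeR tests were checked on simulated data: true changes of 1 on the log2 scale were found in 60.7% of cases in brain and 44% in placenta, and 5.66% and 9.84% of calls were false. The test of the difference between tissues found 24% of such changes, and 9.41% of its calls were false. Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom with sample weights, other count filters, a replicate block, a term for embryo sex, a fit of all 12 libraries together, and leaving out each library in turn. Analyses of resolved rows alone, with and without a trend on exon length, of lists read by the deposited labels, without wild-type replicate 1 of both tissues, and without 2 brain libraries that alone hold genes of other tissues were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 placed the rows and drew the plots. Mitochondrially encoded genes were left out because the tables hold 0 of 37. The 3 libraries in each group limit the precision, and rows at a few CPM rest on few counts. A library was taken to hold a row alone when it had at least 30 counts and the other libraries of its tissue together at most 10% of them.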

Results

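RNA was measured by sequencing in brain and placenta of mouse embryos at embryonic day 19.5. The series asks what Nsd1, a histone H3 methyltransferase, does late in gestation and for survival around birth. Each tissue had 3 wild-type and 3 Nsd1 heterozygous libraries, which the labels give as separate samples, so the p-values measure the spread between samples. Total counts of brain libraries 1 to 3 were 9486322, 7502494 and 6970735 in wild type and 7536862, 7072692 and 10467729 in heterozygotes. In placenta they were 7662730, 8115197 and 9506643 in wild type and 8081731, 10757698 and 8285942 in heterozygotes. The rows labelled with the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together reached 1146 CPM (unscaled) in wild-type brain replicate 1. They reached 896 CPM in wild-type placenta replicate 1, and at most 1.34 CPM in every other library. Rows of the Y chromosome were not resolved, so these are named by their deposited labels. Replicate 1 of each wild-type group was thus the only library with male-level counts, and all heterozygous libraries lacked them.

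Most deposited gene labels did not name the gene whose reads a row held. Rows labelled with the ubiquitous genes Actb and Eef1a1 held 1.52 and 0 CPM in wild-type brain. The counts followed the exons of genes at other places: the median correlation of windows with annotated exons was 0.743 at the best offset and 0.429 at an offset of 0. The best of all scanned offsets is the higher by construction, and the highest correlation over 5 kb from it had a median of 0.672. Correlation alone thus favoured the chosen place only narrowly. Median offsets were 138 kb in size, and only 1363 of the 8490 resolved rows with at least 10 counts (16.05%) lay on the gene of their own label. After reassignment, 46 of 60 brain marker genes with at least 5 CPM were at least 2-fold higher in brain than in placenta, against 39 of 87 by label. For placental markers, 35 of 53 were at least 2-fold higher in placenta, against 43 of 90 by label. All genes below are named by the inferred source gene, and such names can be wrong: 74.4% of pairs of rows given the same source gene lay within 1 log2 unit of each other in their ratio of brain to placenta, against 27.7% of pairs from neighbouring genes.

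**Figure D1:**
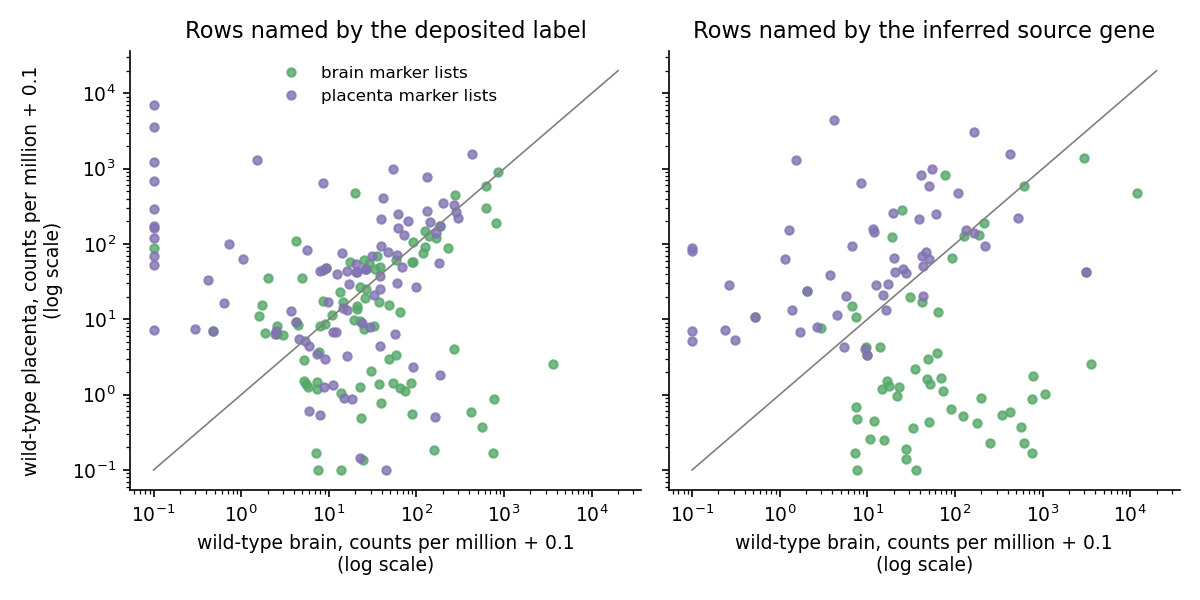
Mean CPM (plus 0.1, log scale) in wild-type brain on the x axis and wild-type placenta on the y axis for genes of brain and placenta marker lists with at least 5 CPM in either tissue, each point a gene. With source gene names, 46 of 60 brain markers and 35 of 53 placental markers were at least 2-fold higher in their own tissue.

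Reads over Nsd1 were lower in heterozygotes of both tissues. Nsd1 lies on chromosome 13 from 55209782 to 55318325 in GRCm38, and its reads were held by the row ENSMUSG00000005320, labelled Fgfr4, which covered 1581 bp of exons 21 and 23. In placenta this row fell from 275 ± 5.10 CPM in wild type to 187 ± 8.82 CPM in heterozygotes (SD, n = 3), a log2 change of -0.55 (SE 0.10, edgeR adjusted p = 0.00834). In brain it stood at 330 ± 13 CPM in wild type and 257 ± 8.87 CPM in heterozygotes, a log2 change of -0.36 (SE 0.10) that did not pass (edgeR adjusted p = 0.0632). Brain Nsd1 had -0.35 and passed (adjusted p = 0.00392) without 2 brain libraries that alone held genes of other tissues. Each heterozygous library lay below each wild-type library of its tissue. A shorter row labelled Uimc1, over 179 bp of Nsd1 exons 3 and 5, fell in brain by 0.96 on the log2 scale (adjusted p = 0.0278) and had -0.06 in placenta (adjusted p = 0.872). The row labelled Nsd1 itself held reads of another place and gave 0.20 in brain and 0.27 in placenta, neither past the threshold.

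**Figure D2:**
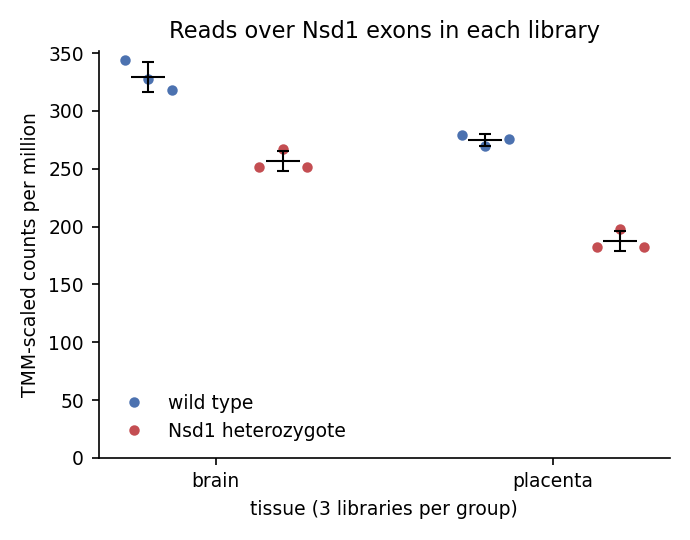
CPM scaled with TMM over Nsd1 exons on the y axis for each library (points, 3 per group) with mean and SD (bars), by tissue on the x axis. Heterozygous libraries averaged 257 against 330 in brain and 187 against 275 in placenta.

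In brain the question was which genes changed with a lower dose of Nsd1. Car8, a carbonic anhydrase-related protein of Purkinje cells, fell from 258 ± 64.3 to 102 ± 13.6 CPM, a log2 change of -1.34 (SE 0.15, adjusted p = 9.33e-05). Pdgfra, the growth factor receptor of oligodendrocyte precursors, fell from 43.7 ± 2.95 to 23.8 ± 6.59 CPM. The epithelial genes Lgals7, a galectin, and Evpl, a protein of the cornified envelope, rose from 2.67 ± 0.839 to 15.6 ± 3.22 CPM and from 17.4 ± 5.68 to 46.3 ± 6.53 CPM. All these values are means and SD of 3 libraries.

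Of 15143 rows tested in brain, 134 passed, 64 higher and 70 lower in heterozygotes. They include 79 resolved rows of 76 source genes, of which 30 rose and 46 fell. The balance of all called rows turned with other settings: 189 were higher and 135 lower with DESeq2, and 60 and 55 with RLE scaling. The groups did not overlap in any of the 134 rows, while 20.5% of all tested rows had no overlap and chance gives 10%. The log2 change was at least 1 in size in 31 rows.

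Predicted genes left out, the 12 largest rises in brain included Lgals7, which rose by 2.53 (SE 0.27), and Evpl, which rose by 1.42 (SE 0.19) on the log2 scale. The predicted gene Gm10451, left out by that rule, rose further, by 3.70 and 3.27 in its 2 rows. Spaca1 rose by 2.52, Tex14 by 2.44, the cardiac myosin Myh6 by 2.41 and the carboxypeptidase Cpa2 by 0.99. Myh6 stood at 3.31 CPM in heterozygotes, and the Tex14 row covers only 108 bp of exons and that of Cdr2l, named next, 143 bp. BC035947 (1.70), CT025671.1 (1.22), Cdr2l (0.86), Cpq (0.74), Cnot10 (0.70), a subunit of the deadenylase complex, and Foxp3 (0.64) completed them. Foxp3 is known from regulatory T cells, and its level of 30.5 CPM in wild-type brain makes the assignment of that row doubtful.

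Among the 12 largest falls in brain by the same rule, Gjc3, a connexin of myelinating glia, fell by 1.86 (SE 0.32) and Ngfr, the low-affinity neurotrophin receptor, fell by 1.72 (SE 0.29) on the log2 scale. The class I histocompatibility genes H2-Q4 and H2-Q2 had log2 changes of -1.63 and -1.40. Samd9l, an interferon-induced growth inhibitor, had -0.92. The citrate transporter Slc13a5 (-1.75), the GABA transporter Slc6a11 (-0.96) and Lynx1 (-1.09), a modulator of nicotinic receptors, also fell. The Slc6a11 row holds only 104 bp of its exons. Ahnak2 (-1.13), the ubiquitin ligase Hecw2 (-1.06) and Pdgfra (-0.86) were the others besides Car8.

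**Figure D3:**
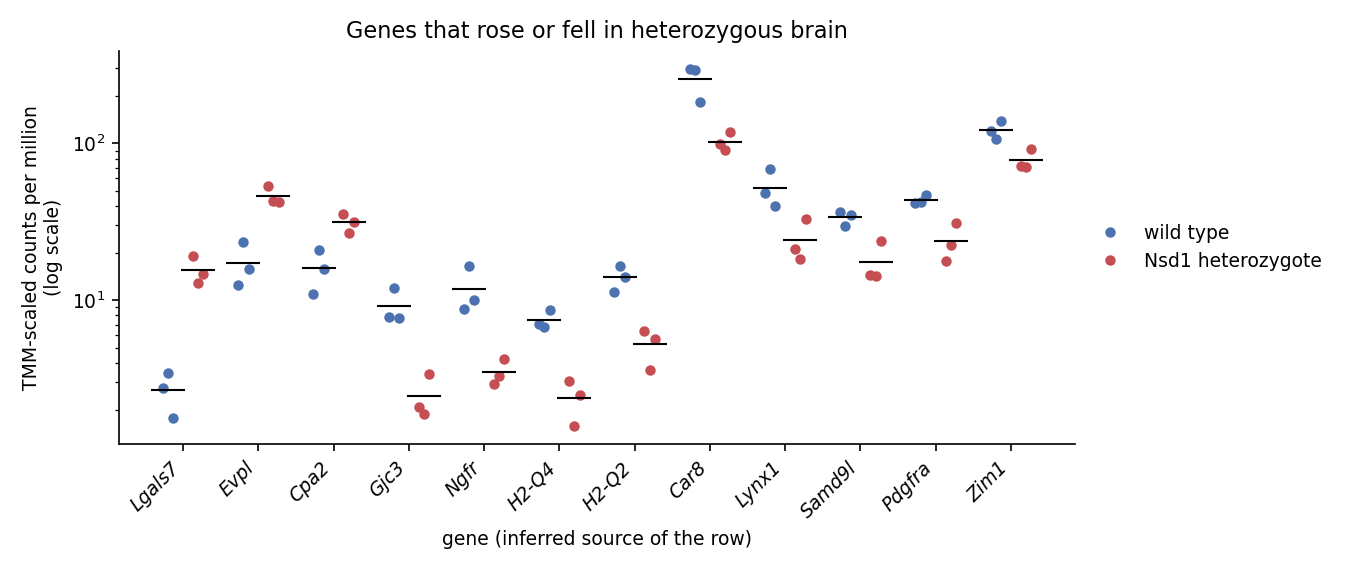
CPM scaled with TMM (log scale, y axis) of 12 genes that passed in brain (x axis), with 3 points per group for single libraries and lines for the means. Car8 averaged 258 in wild type and 102 in heterozygotes, and Lgals7 2.67 and 15.6.

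Interferon response and cholesterol synthesis genes were called lower in brain among 23 lists tested. Of 8 interferon genes, 7 had negative values with a median of -0.59, and none passed over all rows. When adjusted over the list alone 2 fell, Ifit1 (-1.32) and Oas1a (-1.84). Both rest on few counts, with Ifit1 at 4.03 CPM in wild type and 1.58 in heterozygotes and Oas1a at 1.86 and 0.475. The list gave a camera adjusted p = 0.0447, and adjusted p = 0.724 with an estimated correlation. Of 7 cholesterol synthesis genes, 5 fell when adjusted over the list alone and none over all rows: Srebf2 (-0.47), the master regulator of the pathway, Dhcr24 (-0.46), Pcsk9 (-0.51), Lss (-0.26) and Sc5d (-0.25). That list gave a camera adjusted p = 0.0447, and adjusted p = 0.724 with an estimated correlation. None of the list calls of either tissue held with an estimated correlation. That correlation was 0.47 for the cholesterol list, above the preset 0.01. It was below 0.01 for the others: -0.05 for interferon genes in brain, and -0.09 and -0.12 for interferon and macrophage genes in placenta. A higher correlation between genes thus does not account for the loss of those calls.

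Cell type markers of the brain did not pass as lists where tested. The lists of newborn neurons, astrocytes and choroid plexus had under 5 tested genes and were not tested as lists. Of 5 oligodendrocyte lineage genes, Pdgfra fell over all rows. Adjusted over the list alone, Cnp (-0.40) and Cspg4 (-1.16), a proteoglycan of precursors, fell as well, and Sox10 rose (0.31), in a row that holds 189 bp of its exons (camera adjusted p = 0.182). Cnp was -0.26 without wild-type replicate 2 and Sox10 was 0.19 without heterozygous replicate 1. Among 4 markers of newborn neurons, 3 rose when adjusted over the list alone, Stmn1 (0.52), Neurod2 (0.34) and Elavl3 (0.37), and none over all rows. Of 6 cortical layer genes, Pou3f3 rose (0.53, adjusted p = 0.0394), in a row that holds only 105 bp of its exons. Pou3f2 (0.31) rose when adjusted over the list alone. The 19 genes of mature neurons and synapses, with a median of -0.14, held none that passed (camera adjusted p = 0.182), as did 9 radial glia genes (median -0.14) and 10 genes of GABAergic neurons (median -0.05). Markers of the midbrain, hindbrain and cerebellum all had negative values in 5 of 5 genes, with a median of -0.34 and none past the threshold. The 7 macrophage and microglia genes had a median of -0.06 and none passed.

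Chromatin, imprinted and growth genes in brain mostly stayed below the threshold. Of 15 chromatin methylation genes none passed over all rows. Adjusted over the list alone, Nsd1, Tet1 (-0.43) and Ash1l (-0.47) fell and Kdm2a (0.29) rose. Of 20 imprinted genes, the zinc finger gene Zim1 fell (-0.62, adjusted p = 0.0279), and adjusted over the list alone 4 fell, with Calcr (-0.75), Cd81 (-0.39) and, outside the naming rule, the abundant Peg3 (-0.34), and 1 rose, H19 (0.33). Adjusted over the list alone, the cyclin Ccnd2 (0.51) rose among 8 cell cycle genes, and Cdkn1a (-0.55), a cell cycle inhibitor in the glucocorticoid response list, fell among 6 genes of that list, with adjusted p = 0.0529 and 0.0629 over all rows. Rps20 (0.43) and Rps24 (0.30) of 7 ribosomal protein genes also rose over the list alone (camera adjusted p = 0.223). The Rps24 row holds only 107 bp of its exons, and that of Uqcrc2, given next, 122 bp. Adjusted over the list alone, Robo4 (-1.07) of 9 endothelial genes fell, Col1a1 (0.35) rose in the pericyte and fibroblast and the meninges lists, though not in the matrix list, and Ndufs3 (0.48) rose while Uqcrc2 (-0.39) fell among 11 oxidative phosphorylation genes; none of these passed over all rows, and Col1a1 was 0.20 without heterozygous replicate 3. Hypoxia, unfolded protein response, immediate early, growth axis and extracellular matrix lists held no gene that passed.

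The brain count rested on single libraries: it was 9, 8 and 948 without heterozygous replicates 1, 2 and 3 and 24, 862 and 23 without wild-type replicates 1, 2 and 3. A term for embryo sex left 28, with 10 of the 26 named calls. As only wild-type replicate 1 had male-level counts, this is close to leaving that library out, which also kept 10. The fit of all 12 libraries left 8, with 6 of the 26. Some libraries alone held genes known from outside the brain, called genes of other tissues throughout. Heterozygous brain replicate 3 had 375 counts of Mup7, 198 of Cyp2e1 and 63 of Serpina1e, known from liver. Wild-type brain replicate 2 had 141 of Hoxc6 and 80 of Hoxb8, known from the trunk, its spinal cord included. The other 5 brain libraries had 0 in each case, and where these reads came from was not tested. Without these 2 libraries, an analysis chosen after the data were seen and with 2 libraries in each group, 2582 rows passed in brain, the 134 among them, and neither gene list was called. All 26 genes named by rule that had passed did so there, as did 25 of the 29 that had not. Stmn1 was at 0.77, Elavl3 at 0.66, Sox10 at 0.57, Rps24 at 0.50 and, below the threshold, Col1a1 at 0.22. All these genes had been picked by tests on the same libraries, so their passing is no independent support. Of the wild-type brains left there, replicate 1 had male-level Y-linked counts, and the heterozygotes left lacked them.

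In placenta the same question was asked. Macrophage and interferon gene lists were called lower in heterozygous placentas (camera adjusted p = 0.0384 and 0.0485), and both calls were lost with an estimated correlation (adjusted p = 0.485 for each). Gcm1, the transcription factor that drives formation of labyrinth syncytiotrophoblast, rose from 4.74 ± 1.11 to 24.5 ± 9.78 CPM (log2 change 2.37, SE 0.31, adjusted p = 0.00245). Rrm2, a ribonucleotide reductase subunit needed for DNA synthesis, fell from 136 ± 16.3 to 53.6 ± 8.30 CPM (-1.35, SE 0.14, adjusted p = 0.00107). The immediate early gene Fos fell from 104 ± 20.4 to 44.5 ± 5.44 CPM (SD, n = 3 libraries; edgeR adjusted p = 0.00237).

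Of 14414 rows tested in placenta, 1340 passed, 769 higher and 571 lower in heterozygotes. They include 656 resolved rows of 627 source genes, of which 338 rose and 289 fell. Without a filter beyond 1 count 881 rows were higher and 904 lower. In 1327 called rows the groups did not overlap, as in 31.29% of all tested rows, where chance gives 10%. The log2 change was at least 1 in size in 299 rows. The 10 most abundant rows took 15.4 to 16.1% of the counts in wild-type and 19.3 to 20.2% in heterozygous placentas.

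Trophoblast genes moved both ways in placenta. Prl8a1, a placental prolactin-family hormone, rose by 1.77 (SE 0.38), Flt1, the soluble form of which binds placental growth factor, by 0.90 (SE 0.18), and Prl3b1, placental lactogen, by 0.51 (SE 0.13). The lactate transporter Slc16a3 rose (0.82), and the keratin Krt8 rose from 4148 ± 459 to 6164 ± 678 CPM. Of 7 labyrinth genes, Gcm1 and Slc16a3 rose while the growth factor receptors Met (-0.80) and Egfr (-0.72) and the transferrin receptor Tfrc (-0.67) fell, giving a median of -0.67, a mean of 0.00 and a camera adjusted p = 0.688. Of 3 spongiotrophoblast genes Flt1 and Prl8a1 rose, and of 4 progenitor trophoblast genes Krt8 rose.

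Predicted genes left out, the 12 largest rises were led by Fga, fibrinogen alpha (3.37, SE 0.92), which rested on heterozygous replicate 3 at 22.9 CPM; without that library its change was 1.37 and did not pass. Spata21 (2.13) and the collagen Col15a1 (1.81) were highest in heterozygous replicate 2, and without it they were 1.13, which did not pass, and 0.79. The unconventional myosin Myo1g (2.45), the slow troponin Tnnt1 (2.09), the germ cell gene Asz1 (1.99), Plekhd1 (1.88), Igdcc3 (1.86), Shisa7 (1.77) and the retinal protein Rlbp1 (1.71) also rose. Among the 12 largest falls by the same rule were the adhesion receptor Adgra1 (-3.25), the calcium channels Cacna1g (-2.26) and Trpv5 (-1.88), Ceacam-ps1 (-2.14, and -3.28 without heterozygous replicate 3), the GABA receptor subunit Gabre (-2.03), the sphingolipid exporter Spns2 (-1.85) and the nitric oxide synthase Nos1 (-1.81). Col19a1 (-1.70) depended in size on wild-type replicate 1 and was -0.99 without it. Preproenkephalin Penk (-1.65), the hyaluronan receptor Cd44 (-1.62), Cttnbp2 (-1.60) and the matrix protein Fbln2 (-1.60) completed them.

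Macrophage and interferon genes were called lower in placenta among 24 lists tested. All 7 macrophage genes had negative values, with a median of -0.62. Over all rows 3 fell: Csf1r (-0.47), the receptor on which macrophages depend, the complement gene C1qc (-0.76) and the leukocyte phosphatase Ptprc (-1.19). Adjusted over the list alone 5 fell, with Spi1 (-1.12) and Sall1 (-0.62), while C1qc was -0.43 and did not pass without wild-type replicate 3. The list gave a camera adjusted p = 0.0384, and adjusted p = 0.485 with an estimated correlation. All 9 interferon genes had negative values, with a median of -0.45, and Oas2 (-1.19), Ifit1 (-0.56) and Stat1 (-0.56) fell, both over all rows and adjusted over the list alone, though Ifit1 was -0.37 and did not pass without heterozygous replicate 2. That list gave a camera adjusted p = 0.0485, and adjusted p = 0.485 with an estimated correlation.

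**Figure D4:**
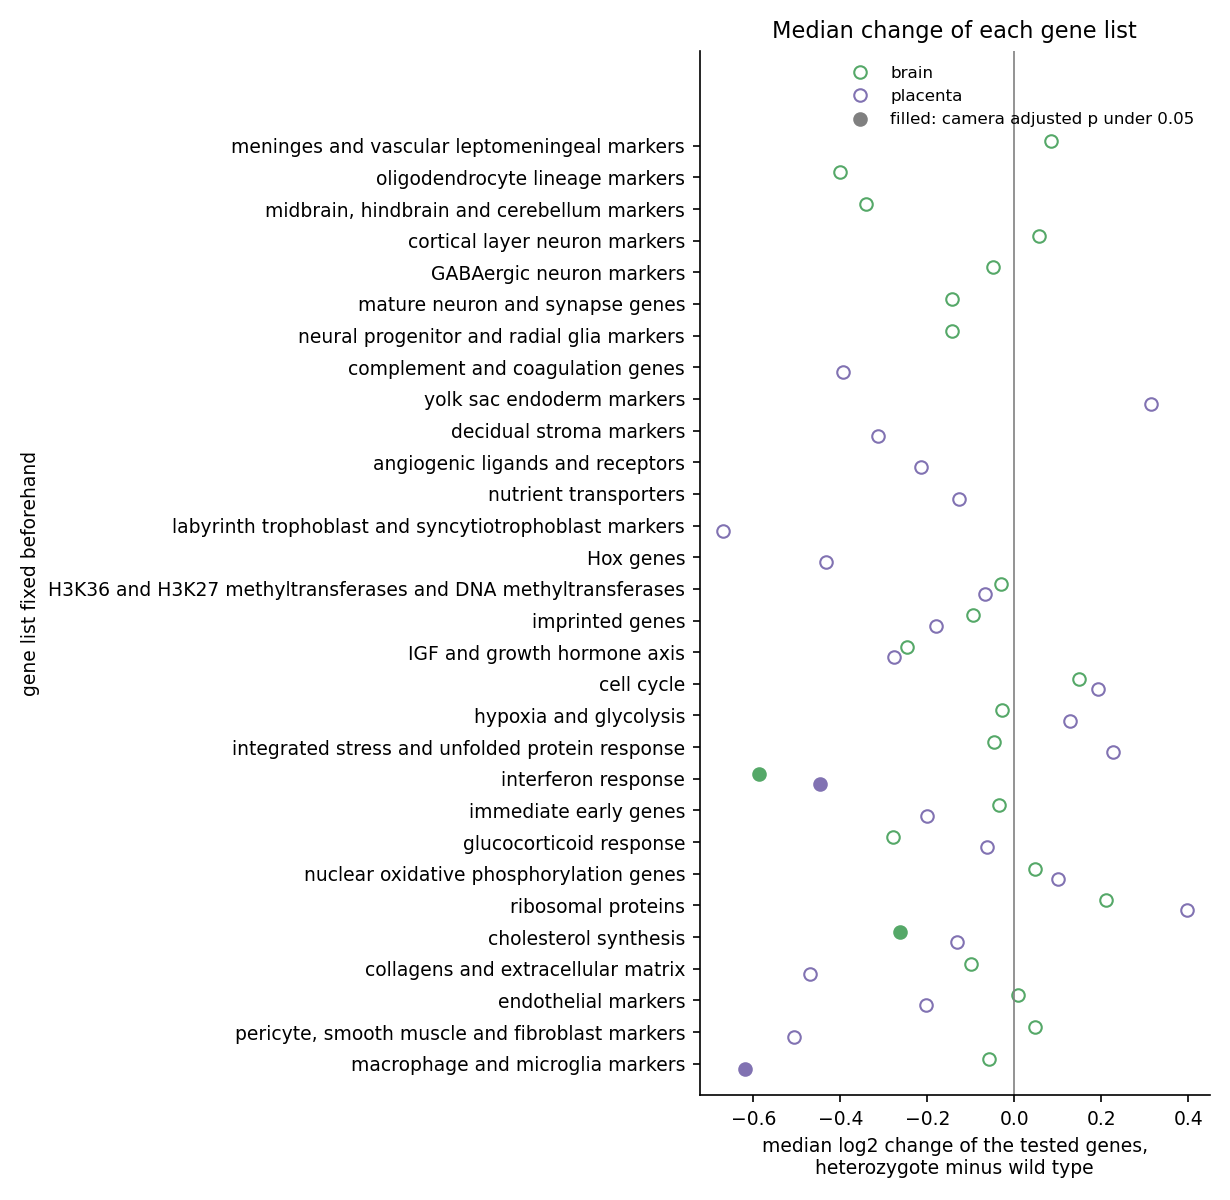
Median log2 change (heterozygote minus wild type, x axis) of the tested genes of each list (y axis), with brain and placenta in separate colours and filled points for a camera adjusted p under 0.05. Macrophage genes had a median of -0.62 in placenta and -0.06 in brain, and interferon genes -0.45 and -0.59.

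Some genes of protein folding and translation rose in placenta. The endoplasmic reticulum proteins Pdia4 (0.76, SE 0.11) and Hyou1 (0.73, SE 0.12) rose, with Pdia4 at 1139 ± 78.4 and 1924 ± 190 CPM, while Vldlr (-1.40) and Nupr1 (-0.55) of the same list fell; its median of 0.23 stood beside a mean of 0.00 and a camera adjusted p = 0.575. Of 6 ribosomal protein genes Rps20 (0.68) and Rps8 (0.44) rose, and 4 rose adjusted over the list alone (camera adjusted p = 0.139). The glycolytic enzyme Tpi1 (0.66) and the hypoxia-induced Higd1a (0.66) rose, Pfkfb3 (-1.0), which drives glycolytic flux, fell, and Slc2a1 (0.48), the glucose transporter, rose only when adjusted over the list alone and was 0.32 without heterozygous replicate 2. The complex I subunit Ndufv1 rose (0.49).

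Imprinted genes moved both ways in placenta, while the 5 growth axis genes all had negative values, with 1 past the threshold (camera adjusted p = 0.393). H19, an imprinted noncoding RNA, rose from 20505 ± 1396 to 31545 ± 4856 CPM (0.62, SE 0.12). Cd81 (-1.26) and Igf2r (-0.59), the receptor that clears insulin-like growth factor II, fell, and Igf2 (-0.65, adjusted p = 0.0867) fell only when adjusted over a list alone, in the growth axis, imprinted and glycogen trophoblast lists, and was -0.43 without wild-type replicate 1. Without heterozygous replicate 1 Igf2r was -0.39 and did not pass. Of 19 imprinted genes 1 rose and 2 fell over all rows, and 2 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.579). Ash1l (-0.70), another histone methyltransferase, fell with Nsd1 among 15 chromatin genes. Hoxa1 (-0.79) was the only member of 5 Hox genes to fall, and all 5 had negative values (camera adjusted p = 0.241).

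**Figure D5:**
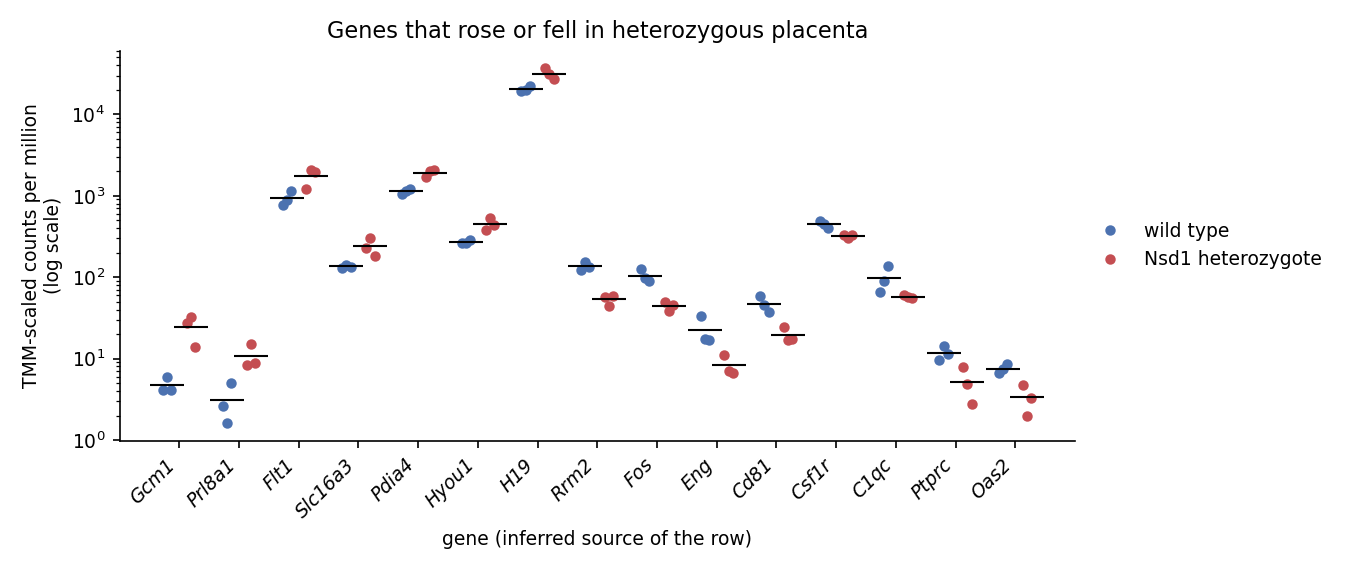
CPM scaled with TMM (log scale, y axis) of 15 genes that passed in placenta (x axis), with 3 points per group for single libraries and lines for the means. Gcm1 averaged 4.74 in wild type and 24.5 in heterozygotes, and Rrm2 136 and 53.6.

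Vessel, stroma and blood genes were mixed in placenta. The endothelial coreceptor Eng (-1.44) and the adhesion molecule Pecam1 (-0.58) fell, as did Pdgfb (-0.86), Pdgfra (-0.57) and fibronectin Fn1 (-0.69), while none of the endothelial (median -0.20), stromal (-0.51), matrix (-0.47) or decidual lists (-0.31) was called. The annexin Anxa5 (0.79) rose and the protease inhibitor Tfpi2 (-0.78) fell among 9 coagulation genes; without heterozygous replicate 2 Tfpi2 was -0.50 and did not pass. Of 17 nutrient transporters the amino acid transporter Slc7a8 (-0.96) fell over all rows, and 4 rose and 5 fell adjusted over the list alone. Klf4 (-0.61) fell and Dusp1 (0.59) rose among 10 immediate early genes. Of 7 cell cycle genes only Rrm2 passed, and Srebf2 (-0.73) was the only one of 6 cholesterol synthesis genes to pass. The granzyme Gzme (2.81) rose on heterozygous replicate 1 and was 1.06 and not past the threshold without it. Erythroid (median -0.71), glucocorticoid, glycogen trophoblast, neutrophil and steroid synthesis genes held none that passed over all rows.

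The placenta count was 170 without wild-type replicate 2, 454 without wild-type replicate 1, and 446 and 547 without heterozygous replicates 2 and 3. A term for embryo sex left 460, with 35 of the 66 named calls. This too is close to leaving out wild-type replicate 1, which also kept 35. Without wild-type replicate 2 or 3 neither gene list was called. Wild-type replicate 1 had 137 counts of Krt5 and 85 of Krt1, keratins of the epidermis, against 4 and 1 in the other 5 placental libraries together.

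A test of the difference between tissues asked which genes responded otherwise in placenta than in brain. Among 18289 rows tested, 10 passed, 4 with a higher and 6 with a lower change in placenta, and 1799 had an unadjusted p under 0.05. On simulated data this test found 24% of log2 differences of 1 and 1.7% of those of 0.58. So few calls therefore do not show that the tissues responded alike. The synaptic gene Shisa7 changed by 1.82 in placenta and -0.16 in brain in this fit, a difference of 1.98 (SE 0.32, adjusted p = 0.0224). The synaptic vesicle gene Svop (2.29) and the ephrin Efna3 (1.82) also had higher changes in placenta, and Cttnbp2 (-1.51) a lower one. A row of Srcin1 (-2.02) and a row of the phosphatase Ptprs (-1.44) had lower changes too, but the rows with the most counts of these genes gave 0.10 and -0.50 and did not pass. These genes are known from neurons, and in placenta their rows stood at 0.514 to 18.4 CPM (unscaled). Without the 2 brain libraries that alone held genes of other tissues 15 rows passed, and Cttnbp2 (-1.32) and the Srcin1 row (-1.97) did not. Leaving out single libraries gave 0 to 23 rows, with 0 without heterozygous brain replicate 1 or 2 or wild-type placenta replicate 2.

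The last comparison asked whether both tissues changed in the same genes. Of 11731 rows tested in both, 34 passed in both and in the same direction, and 0 in opposite directions. Among the shared falls, Scd2, a fatty acid desaturase, had log2 changes of -0.83 in brain and -1.16 in placenta, and Acly, which makes cytosolic acetyl-CoA, -0.57 and -0.93. Other rows hold more counts of both genes: that of Scd2 gave -0.43 and -0.55, neither past the threshold, and that of Acly -0.24, which did not pass, and -0.71, which did. Without wild-type replicate 1 the Scd2 row was -0.70 in placenta and did not pass. The receptor genes Pdgfra (-0.86 and -0.57) and Il6st (-0.59 and -0.51), the signal transducer of interleukin-6 family cytokines, fell in both. So did H2-Q4 (-1.63 and -0.96), Samd9l (-0.92 and -1.13) and Pde10a (-0.72 and -1.26), a phosphodiesterase. Igdcc3 (0.61 and 1.86), Cnot10 (0.70 and 0.70), the splicing factor subunit Phf5a (0.63 and 0.93) and the proteasome subunit Sem1 (0.49 and 0.51) rose in both. The 15 shared rises compare with 3.11 for independent lists (one-sided Fisher exact p = 2.22e-07) and the 19 shared falls with 1.94 (p = 9.45e-15), with rows counted as independent. The labels do not say whether the brain and the placenta of a number come from 1 embryo, and these p-values and the test of the difference between tissues take the tissues as independent. Across all rows the changes in the tissues correlated with r = 0.385, over rows that are not independent replicates. Without wild-type replicate 1 of both tissues 3 rows were shared, against 0.271 for independent lists, leaving out single libraries gave 2 to 312, and without the 2 brain libraries that alone held genes of other tissues 601 rows were shared, the 34 among them, and 11 went in opposite directions.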

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

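Of the tests in this part, the other splits of the samples, the order of the labels, the share on chromosome 13 and both macrophage tests were chosen only after the result was seen, and the fits without wild-type replicate 1 of both tissues and without the length trend were added after the data were seen. The 10 rows whose genotype effect differed between placenta and brain stand out because the difference itself passed the interaction test. Their named genes, as log2 change in placenta minus that in brain, were Shisa7 at 1.98, Svop at 2.29, Efna3 at 1.82, Srcin1 at -2.02, Ptprs at -1.44, Cttnbp2 at -1.51 and Adgrb1 at -6.31. For Srcin1, Ptprs and Adgrb1 another row holds more counts, with 0.10, -0.50 and -1.97, and none of these passed. Adgrb1 had 28 counts over the wild-type placentas and 0 over the heterozygous ones, so its fitted value is no measure of size, and against a limit of 3 counts over the group it was at least 10.0-fold lower. Chance is not excluded for the count of 10: in 9 of 100 splits as many rows passed, and the highest other split gave 130. These 9 are the real grouping and 8 that kept the placental genotypes and regrouped the brains. No split with regrouped placentas gave more than 2. The real placental grouping was also the only one with calls within placenta, 1340 rows, so this is no separate support for an effect of genotype.

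Most rows did not hold the reads of the genes on their labels; 16.05% of resolved rows lay on their own gene. Labels in another order than the counts are argued against by pairs of rows given the same source gene, whose ratios of brain to placenta correlated with r = 0.862 across pairs. Reads and gene coordinates from different genome builds may account for the pattern: 51% of 828 pairs of neighbouring windows without shared rows chose offsets within 2500 bp of each other, against 2.02% with windows permuted. No annotation of a build other than GRCm38 was at hand for a direct test, and no biological explanation was tested.

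The 34 rows that passed in both tissues in the same direction are the pattern that carries over between the tissues. Splits of the samples decide nothing here: every regrouped split of either tissue gave 0 rows, so the shared count was 34 in 1 of 200 splits, the real grouping, and 0 as the highest other. Without wild-type replicate 1, the only library with male-level Y-linked counts in each tissue, the changes kept a median of 0.899 of their size over both tissues. The lowest share was 0.606, in placenta. Embryo sex is not decided by this: the rows were picked with that library included, and in all 134 brain calls the groups did not overlap. Without that replicate in both tissues 3 rows passed in both, against 0.271 for independent lists, from tests with fewer libraries. All libraries left there lacked male-level Y-linked counts, which argues against embryo sex for these 3 rows. A term for embryo sex left 28 brain and 460 placenta rows. With 1 male-level library in each tissue, the term acts much like leaving that library out, which left 24 and 454. It is thus no separate check. Other explanations were tested in part. With a trend on transcript length removed, the 21 shared rows resolved to 1 gene kept 0.962, and the other 13 were not run. The trend itself was small, with median changes of -0.19 to 0.07 over 5 bins of length. It could thus make up only a part of the sizes of these rows. The rows were picked with the trend included, and the number shared without it was not counted. On chromosome 13 lay 3.85% of the placed rows, which leaves little room for alleles linked to Nsd1. An effect of the Nsd1 genotype remains a hypothesis, with embryo sex undecided for all but those 3 shared rows and litter and unlinked strain alleles untested.

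All 7 macrophage markers had negative values in heterozygous placenta and 3 passed. The list's call was lost in camera with an estimated correlation (adjusted p = 0.485), though that correlation, -0.12, lay below the preset 0.01. It was also lost with the replicate block (adjusted p = 0.0591) and without wild-type replicate 2 or 3 (adjusted p = 0.11 and 0.123). Over all settings its adjusted p ranged from 0.00863 to 0.754. The share of counts outside the 10 most abundant rows changed by -0.068 log2, a small part of the list's median of -0.62. The list's values are scaled with TMM, which already allows for such rows, so this unscaled share decides little about them. A lower share of macrophages in the sampled tissue may account for it, as the intervals of plus and minus 2 SE of 6 of the 7 markers held their weighted mean of -0.54, although wide intervals make this easy to meet. Erythroid (median -0.71), stromal (-0.51) and matrix lists (-0.47) lay about as low and were not called. Lower expression per macrophage was not tested and stays open, as does the sampling of the placenta and its decidua.

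With 3 against 3 libraries there are only 10 splits, too few for a share under 0.05. The real split of the brains gave 134 rows, the largest result in 1 of 10 splits, and the highest other gave 0. The real split of the placentas gave 1340 rows, again the largest in 1 of 10, and the highest other gave 0. For gene lists, 2 of 10 splits of the brains gave as many as the real 2, with 2 as the highest other, and 3 of 10 splits of the placentas did, with 3 as the highest other.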

How the results depend on the processing

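The fits of resolved genes alone, the length trend, the lists by deposited label, the overlap without wild-type replicate 1 of both tissues and the fits without wild-type brain replicate 2 and heterozygous brain replicate 3, which alone hold genes of other tissues, were chosen after the data were seen. No named gene changed direction under the alternatives that tested it. The count of brain rows that passed (134) was 324 with DESeq2, 1604 with limma-voom, 539 without a filter beyond 1 count, 28 with a sex term, 8 in the fit of all 12 libraries, 50 with resolved genes only, 88 with resolved genes only and the length trend removed, and 2582 without those 2 brain libraries. RLE scaling gave 115 and a filter at 1 CPM 108. The placenta count (1340) was 460 with a sex term, 722 with resolved genes only and 659 with resolved genes only and the length trend removed, and 1316 to 1789 under the other settings. In the fits of all rows, 79 resolved rows had passed in brain and 656 in placenta. Among resolved rows the count thus fell to 50 in brain and rose to 722 in placenta. The cause of the shifts was not tested. The share of these rows that were higher in heterozygotes was 47.8% in brain, over a range of 42.9 to 87.5% with a single library left out or another setting, and 57.4% in placenta, over a range of 49.4 to 62.9%.

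Leaving out 1 library gave 8 to 948 brain rows: 24, 862 and 23 without wild-type replicates 1, 2 and 3, and 9, 8 and 948 without heterozygous replicates 1, 2 and 3. It gave 170 to 1401 placenta rows, with 454 and 170 without wild-type replicates 1 and 2 and 446 and 547 without heterozygous replicates 2 and 3. Of 26 named brain calls, 4 to 25 kept their call in these fits, and of 66 placenta calls 17 to 52. The sex term kept 10 and 35 of them, the same numbers as leaving out wild-type replicate 1, and the fit of all 12 libraries 6 and 58. The other settings kept at least 24 of 26 brain calls and 57 of 66 placenta calls, and DESeq2 13 of 13 and 55 of 61 that had an adjusted p.

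The lists called in brain (2) were 0 with an estimated correlation, 0 with fry, 1 with the replicate block, 1 with a sex term, 0 without those 2 brain libraries, 0 by deposited labels, where the interferon list turned upward (adjusted p = 0.985, over a range of 0.00637 to 0.985), and 0 to 2 with a library left out; wild-type replicates 1 and 2 each took away both. The lists called in placenta (2) were 0 with an estimated correlation, 0 with the replicate block, 1 by deposited labels, another list and upward, and 0 to 3 with a library left out, with 0 without wild-type replicate 2 or 3 and 3 without heterozygous replicate 1. The sex term and fry kept both.

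The difference between tissues (10) was 125 with DESeq2, 198 without a filter, 18 with a replicate block, 15 without those 2 brain libraries and 0 to 23 with a library left out. It was 0 without heterozygous brain replicate 1 or 2 or wild-type placenta replicate 2; 6 and 3 without wild-type brain replicates 2 and 3, 4 without wild-type placenta replicate 3 and 5 without heterozygous placenta replicate 2; and 23, 20 and 18 without heterozygous brain replicate 3 and heterozygous placenta replicates 1 and 3. The overlap (34) was 314 at an unadjusted p under 0.01, 3 without wild-type replicate 1 of both tissues, 601 without those 2 brain libraries, and 2 to 312 with a library left out: 5 without wild-type brain replicate 1 or 3, 2 without heterozygous brain replicate 1 or 2, 312 and 217 without wild-type brain replicate 2 and heterozygous brain replicate 3, 14 and 8 without wild-type placenta replicates 1 and 2, and 15 and 17 without heterozygous placenta replicates 2 and 3. It stayed 4.10 to 13.1 times the number for independent lists in every case.

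Equal replicate numbers of wild type and heterozygote correlated across rows, which are not independent replicates, with r of -0.08, -0.07 and -0.06 in brain and 0.05, -0.11 and 0.06 in placenta, which shows no pairing. Brain with placenta of equal number had 0.19, 0.12 and -0.02 in wild type, with unequal numbers at -0.23 to 0.13, and -0.04, 0.06 and 0.01 in heterozygotes, so whether they come from 1 embryo stays open. With the block, 113 brain rows and 1789 placenta rows passed, and 34 were shared, of which 24 are among the 34 shared without it. On simulated data, 22.7% of log2 changes of 0.58 were found in brain and 11% in placenta, so most changes of that size were missed; depth and number of libraries were not varied.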

Other observations

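The genes and the test of this part were chosen after the values were seen, and the genes were not tested as groups. The predicted gene Gm10451 on chromosome 12, outside the naming rule, had the largest shared rises, by 3.70 and 3.27 in brain and 2.23 and 1.94 in placenta on the log2 scale in its 2 rows. In placenta the thioredoxin-like Erp44 (0.67) rose, while the fixed unfolded protein response list was not called (camera adjusted p = 0.575). The inhibitory receptor Lilrb4a (-1.31) and the interferon-induced GTPase Tgtp1 (-1.15) fell. The histone methyltransferase gene Kmt2c (-0.95) fell, while the fixed chromatin list was not called (camera adjusted p = 0.827). All these rows passed in each of the 6 fits of their tissue that leave out 1 library.

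Changes fell with the length of transcripts in both tissues. Across rows, Spearman's rho of log2 change and exon length was -0.18 in brain and -0.19 in placenta, over genes that are not independent replicates. With rows in 5 equal bins of length, the median change of the shortest bin was 0.07 in both tissues, and that of the longest was -0.10 in brain and -0.19 in placenta. Of 100 called rows in the longest bin in placenta 23 were higher in heterozygotes, and of 172 in the shortest 132 were. Rows over introns held 1.92 to 2.31% of the placed counts in every library.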
